A study of Mus musculus with 6 samples.

How the data were processed

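Total RNA from quadriceps femoris of Prr14-WT and Prr14-KO mice was prepared with TRIzol, made into cDNA by template switching, amplified in 14 PCR cycles and read on an Oxford Nanopore PromethION instrument, per the labels' protocols. Each genotype has 3 libraries, numbered here 1 to 3 in accession order. Per the submitters' processing notes, the tools include minimap2 (version not given) and DESeq2 1.6.3, and the genome build is GRCm38. The read counter, the annotation release and the use of strand are not given in the sources used here.

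The deposited counts are whole numbers of reads per Ensembl gene for 22036 genes, not normalized, per the file headers. The authors also deposited CPM for the same genes, which are the counts divided by a fixed total per library that is larger than the sum over the listed genes. The listed genes therefore held all but 3.36 ± 0.244% (WT) and 3.91 ± 0.165% (KO) of that total. The deposited CPM served only to find these totals. Gene symbols were taken by Ensembl identifier from a reference table, which held 22022 of the identifiers, because 27 symbols in the deposited table had turned into dates. Positions are from GENCODE M21 on GRCm38.

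Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by genotype with its defaults (minimum count 10, minimum total 15) left 6680 genes, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion compared KO with WT. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Printed CPM use the TMM-scaled library sizes. Principal components were taken from log2 CPM with a prior count of 2.

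Before the data were examined, 32 gene lists were fixed. The sex-linked list was not tested, and the other 31 were tested with camera at a preset correlation of 0.01, which compares a list's genes with all other tested genes. With a correlation estimated per list, 0 of the 31 lists passed, against 8 with the preset value. The fry test, which asks whether a list's genes move on balance one way and makes no comparison with other genes, passed 5 lists, and its form for either direction passed 16. Among the 16 were both MEF2 lists and the nuclear envelope, tricarboxylic acid cycle, fatty acid, atrophy, satellite cell, clock and ribosome lists. Camera did not pass these in the main test. Named genes followed a rule fixed at the same time: Prr14, Prr14l, Mef2c and the 6 myosin heavy chain genes, the 10 largest rises and 10 largest falls among passing genes with no overlap between genotypes and a mean of at least 5 CPM, and up to 4 members with the smallest p in the direction of the test from each list that passed or held a passing gene. Other changed list members named in the report, and Mef2a, Mef2d, Trim63, Fbxo32, Lmna and Cbx5, were chosen after their values were seen. Some genes that the rule or a count covers are not reported here.

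The same steps were tested on simulated counts for the KO against WT comparison (6680 genes, 200 of them changed). Of the changed genes that passed the filter, 20.8% were called at 1.5-fold, 53.1% at 2-fold, 93.0% at 4-fold and 100% at 8-fold. Of 129 calls, 9 were false (6.98%). With no simulated change 6 genes and 1 list were called. Simulated genes were drawn independently, so this count does not give the false rate for lists whose genes vary together. In the data the estimated correlation within a list ranged from -0.125 (cell cycle) to 0.973 (red blood cell). Changes under 2-fold are therefore often missed at this depth.

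At 3 counts a gene stands at 1.72 to 2.19 CPM in a library. Ratios for genes with 1 to 3 counts in a group have exact binomial 95% intervals. The reads carry no molecular identifiers, so intervals and floors cover counting error only. Pairs of libraries within a genotype had a Pearson chi-square per degree of freedom of 2.19 to 5.35, where 1 library read again would give about 1. Repeat libraries of one animal could differ as much after amplification, so this does not show that the libraries come from separate animals, and n follows the labels. Reads of overlapping genes and of near-identical paralogs could have been split between them by the authors' counting.

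Alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling in edgeR, leaving the 20 most abundant genes out of library sizes, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, voom in limma 3.58.1, robust=FALSE, each library left out in turn, and windows of 5 and 20 Mb around Prr14. Library totals without TMM and a slow-fibre score as a covariate were added after the data were seen.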

Results

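Total RNA from the quadriceps femoris, the large muscle at the front of the thigh, was sequenced as nanopore cDNA in 3 wild-type (WT) libraries and 3 libraries of Prr14-knockout (KO) mice. PRR14 is a protein of the nuclear periphery that tethers heterochromatin to the lamina. The series title names mechanotransduction, myofibre identity and MEF2C, so the comparison asks which muscle genes differed in level between the genotypes. The listed genes held between 1436099 and 1712975 read counts per library, and 11930 ± 257 genes in WT and 12130 ± 91.9 in KO had at least 1 count (SD, n = 3 each). Levels are CPM, read counts scaled to a common library size by TMM, and errors are SDs over 3 libraries unless an SE is named. The labels name the mice only through the sample titles, so p-values measure the spread between these libraries.

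The targeted gene was read at low depth. Prr14 (ENSMUSG00000030822, GRCm38 chromosome 7, 127459611 to 127476759, plus strand, protein coding) had 9, 11 and 12 counts in WT replicates 1 to 3 and 4, 10 and 3 counts in KO replicates 1 to 3. Its level was 7.43 ± 0.83 CPM in WT and 3.47 ± 2.43 CPM in KO (n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). The log2 fold change was -1.10 (SE 0.46, edgeR adjusted p = 0.196), so a difference was not established at this depth. The library labelled KO replicate 2 held the 10 counts, and without it the log2 fold change was -1.80 (edgeR adjusted p = 0.080). The part of the gene removed in the knockout is not given in the sources used here, so reads outside it would not check the label. Its paralog Prr14l was too low to be tested, at 5.37 ± 1.7 CPM in WT and 2.59 ± 1.2 CPM in KO.

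Of 6680 genes tested, 199 were higher and 219 were lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 100 and 122 of these differed by at least 2-fold. At an unadjusted p under 0.05 the count was 1333. The libraries of the genotypes did not overlap for 1721 tested genes (25.8%, against 10% by chance). The first principal component held 44.7% of the variance and separated the genotypes, with WT libraries between -22.88 and -17.91 and KO libraries between 14.74 and 26.93, and the second held 18.7%. Spearman correlations across genes were 0.925 to 0.947 within a genotype and 0.885 to 0.920 between them. The 20 most abundant genes took 41.7 ± 2.85% of counts in WT and 35.4 ± 1.4% in KO (exact two-sided permutation p = 0.1, the smallest possible), and TMM factors were 0.923 ± 0.055 and 1.085 ± 0.027. With library totals in place of TMM the split was 653 higher and 148 lower, and the median log2 fold change of all tested genes was 0.251 in place of 0.017, so changes are given relative to the TMM scale.

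**Figure D1:**
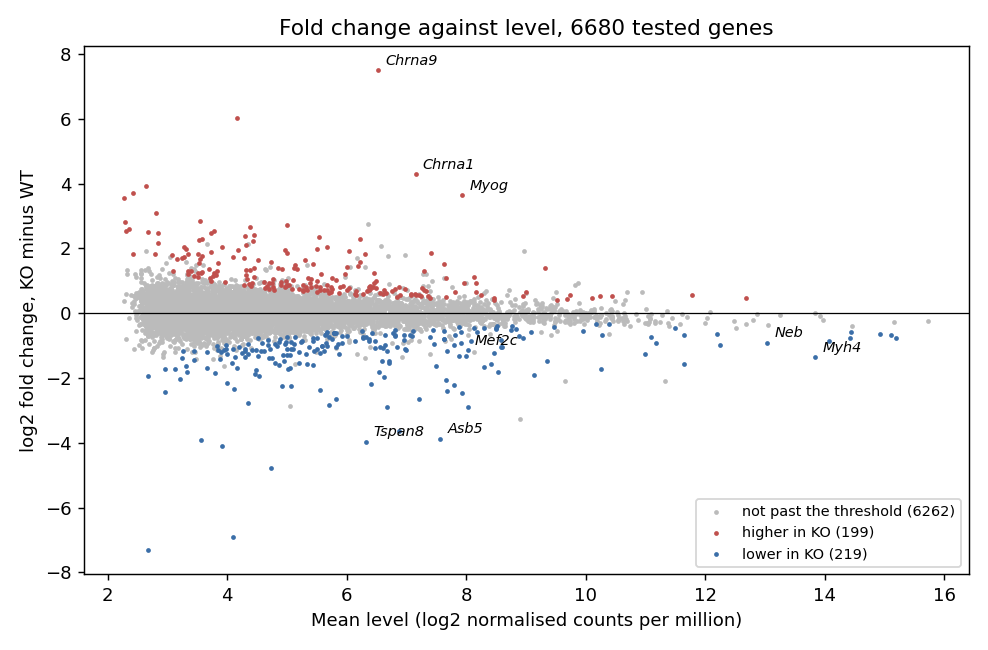
Each point is 1 of the 6680 tested genes, with the mean level in log2 normalised CPM on the horizontal axis and the log2 fold change (KO minus WT) on the vertical axis. The 199 genes higher in KO and the 219 lower in KO are coloured, and Chrna9 has the highest log2 fold change, 7.51.

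Fast-fibre contractile genes were lower in KO muscle. Myh4, the myosin heavy chain of the fastest fibres (type IIB), went from 21073 ± 2343 to 8214 ± 1137 CPM (log2 fold change -1.36, SE 0.12, edgeR adjusted p = 6.73e-06). Of the 15 fast-fibre genes measured, 7 fell, 0 rose and 8 did not pass, and 12 fell adjusted over the list alone. Without KO replicate 1, 4 fell: the calls for Myl1, Tpm1 and Pvalb were lost (edgeR adjusted p = 0.19, 0.107 and 0.317). That for Tpm1 was also lost without KO replicate 2 (0.058), and that for Pvalb without WT replicate 1, 2 or 3 or KO replicate 2 (0.0515 to 0.122), and with upper-quartile scaling (0.0502) and library totals (0.0743). The fast myosin light chain Mylpf, the fast troponin C gene Tnnc2 and the calsequestrin gene Casq1 fell by 0.76, fell by 0.67 and fell by 0.73 on the log2 scale. Mylpf is also the changed gene nearest to Prr14, at 0.245 Mb. The fast-fibre list was lower as a set (median -0.65, or -0.41 with library totals, camera adjusted p = 5.17e-10; adjusted p = 0.416 with an estimated correlation).

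The other adult myosin heavy chains varied more between libraries. Myh1 (type IIX) had 4150 ± 981 CPM in WT and 982 ± 677 CPM in KO (log2 fold change -2.08, SE 0.58, edgeR adjusted p = 0.157), and it passed as lower with all 6 libraries under DESeq2 (adjusted p = 0.0157), limma-voom (0.00263) and robust=FALSE (0.00652), and without KO replicate 2 (edgeR adjusted p = 0.000115), and with the slow-fibre score as a covariate (0.0138). Myh2 (type IIA) had 391 ± 235 and 171 ± 158 CPM (edgeR adjusted p = 0.580). Myh7, the slow type I myosin, had 59.8, 40.9 and 2.05 CPM in WT replicates 1 to 3 and 0.612, 84.3 and 0.573 CPM in KO replicates 1 to 3 (edgeR adjusted p = 0.962). With the slow-fibre score as a covariate, a setting chosen after seeing the data whose score contains Myh7 itself, Myh7 passed as lower (log2 fold change -2.092, edgeR adjusted p = 0.005). As a share of the 4 adult heavy chains, Myh4 made up 82.1 ± 4.59% of counts in WT and 87.5 ± 9.02% in KO (exact two-sided permutation p = 0.4). Myh3 and Myh8, the embryonic and neonatal forms, were too low to be tested; Myh8 had 1.88 ± 0.90 and 5.48 ± 1.80 CPM. Of the 4 myosin heavy chain genes tested 1 fell (2 adjusted over the list alone), and the list was lower (camera adjusted p = 0.000477; adjusted p = 0.227 with an estimated correlation). Of 12 slow-fibre genes 1 rose, both over all genes and adjusted over the list alone: Casq2, from 15.8 ± 1.69 to 41.9 ± 10.2 CPM. The slow-fibre list did not pass (camera adjusted p = 0.473), and its mean log2 CPM was 5.70, 5.33 and 2.66 in WT replicates 1 to 3 and 4.61, 6.77 and 3.30 in KO replicates 1 to 3.

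**Figure D2:**
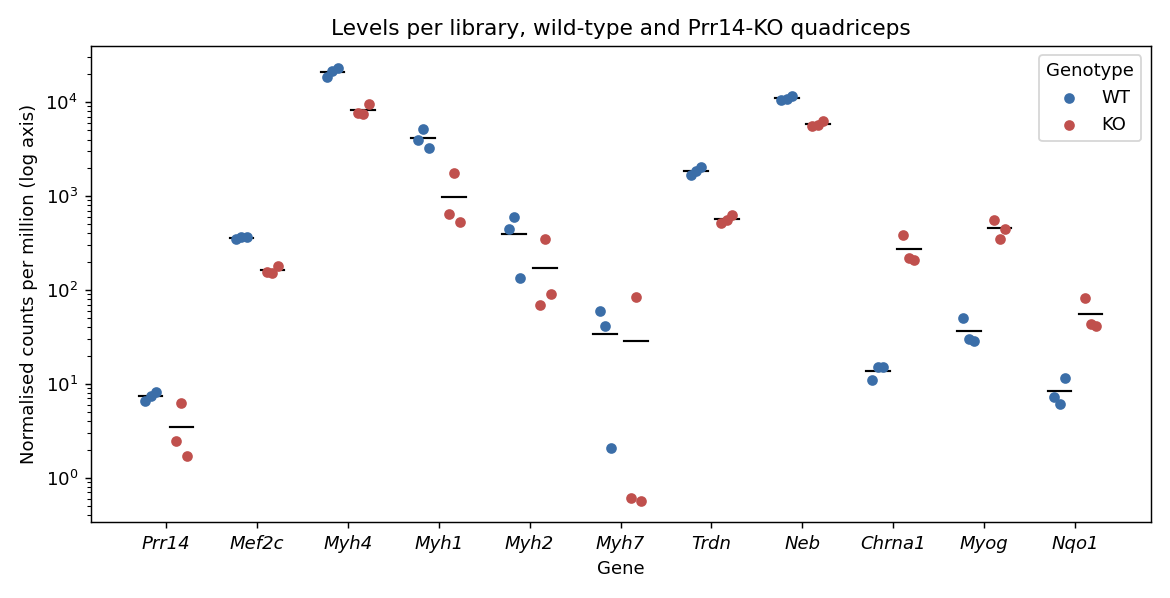
Points are single libraries (WT blue, KO red, 3 each), bars are means, and the vertical axis is normalised CPM on a log scale. Prr14, Mef2c, Myh4, Myh1, Trdn and Neb lay lower in each KO library than in each WT library, Chrna1, Myog and Nqo1 lay higher, and Myh7 ranged from 0.573 to 84.3 CPM within KO. Of these, Prr14, Myh1 and Myh7 did not pass in the main test.

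Mef2c, the transcription factor named in the series title, fell from 359 ± 9.65 to 162 ± 16.6 CPM (log2 fold change -1.15, SE 0.12, edgeR adjusted p = 2.50e-05; ENSMUSG00000005583, GRCm38 chromosome 13, 83504034 to 83667080, plus strand). Mef2a and Mef2d, its relatives, did not pass, with log2 fold changes of 0.34 and 0.39, though Mef2d passed with library totals (edgeR adjusted p = 0.0419). Of 14 tested MEF2 factors and regulators 2 fell and 0 rose (3 fell and 1 rose adjusted over the list alone). The second was Ppp3ca, a catalytic subunit of calcineurin, at -0.97 (edgeR adjusted p = 0.039), and its call was lost without WT replicate 1, 2 or 3 or KO replicate 1 or 2 (edgeR adjusted p 0.056 to 0.119), and with DESeq2 (0.0603), robust=FALSE (0.0522) and library totals (0.0737). Of 15 MEF2 targets in muscle, Myog rose while Xirp2 and Myom1 fell (2 rose and 3 fell adjusted over the list alone). With library totals Hrc and Slc2a4 also passed as higher (edgeR adjusted p = 0.0101 and 0.0194), and Actn2, on this list as well, passed in the settings given below. Neither list passed camera as a set (adjusted p = 0.215 and 0.573). Both passed the form of fry for either direction (adjusted p = 0.000499 each), which makes no comparison with other genes.

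Among structural genes of the sarcomere, Nexn, Neb, Acta1, Myom1 and Ttn fell. Of 31 tested sarcomere and Z-disc genes 5 fell, 0 rose and 26 did not pass, and adjusted over the list alone 9 fell and 4 rose. Actn2, a Z-disc actinin, did not pass in the main test (log2 fold change 0.86, edgeR adjusted p = 0.0717) and passed as higher with no filter (1.46e-10), DESeq2 (0.00242), limma-voom (0.0244), robust=FALSE (0.0227), without WT replicate 3 (0.0467) and with the slow-fibre score as a covariate (0.000489). Up to 5 genes of the list passed as higher in an alternative. Nexn, an actin-binding Z-disc protein, fell from 335 ± 21.3 to 135 ± 1.65 CPM (log2 fold change -1.31, SE 0.12). Neb (nebulin) went from 11007 ± 586 to 5866 ± 323 CPM, and Ttn (titin) and the skeletal actin gene Acta1 fell by 0.97 and fell by 0.66 on the log2 scale. The call for Ttn (edgeR adjusted p = 0.0138) was lost without WT replicate 3 (0.0526) or KO replicate 2 (0.0598). The list was lower as a set (median -0.15, camera adjusted p = 0.0154; adjusted p = 0.227 with an estimated correlation). With library totals the list's median was 0.087 while its test still pointed lower relative to the other genes (camera adjusted p = 0.0418).

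Genes of calcium release and of the membrane contacts that couple excitation to contraction were lower in KO. Trdn (triadin, a calcium release complex protein) went from 1869 ± 177 to 569 ± 61.0 CPM (log2 fold change -1.72, SE 0.11, edgeR adjusted p = 4.25e-07). The junctophilin genes Jph1 and Jph2, which hold these membranes together, fell by 1.10 and fell by 1.53 on the log2 scale. Of 26 tested genes 9 fell, 1 rose and 16 did not pass, and adjusted over the list alone 12 fell and 1 rose. The gene that rose was Casq2, the cardiac and slow-fibre calsequestrin, also on the slow-fibre list. In the alternatives 6 (library totals) to 11 (no filter) fell. The call for Cacna1s was lost without WT replicate 2 (edgeR adjusted p = 0.115) or 3 (0.0547) and with library totals (0.0596). That for Asph was lost with library totals (0.0593), and that for Pvalb in the settings given above. Casq1, Pvalb and Atp2a1 are also on the fast-fibre list, so these lists overlap. The list was lower as a set (median -0.43, or -0.19 with library totals, camera adjusted p = 9.16e-07; adjusted p = 0.132 with an estimated correlation).

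Genes of the neuromuscular junction and of the response to denervation were higher in KO. Chrna1, the alpha subunit of the muscle acetylcholine receptor, rose from 13.7 ± 2.36 to 271 ± 98.9 CPM (log2 fold change 4.30, SE 0.29, edgeR adjusted p = 1.01e-05). Myog (myogenin), a myogenic transcription factor, rose from 36.4 ± 12.1 to 453 ± 104 CPM. Lrp4 and Musk, which together receive the nerve signal agrin, rose by 1.83 and 1.72 on the log2 scale. Ache and Chrnb1, the synaptic acetylcholinesterase and a receptor subunit, also rose. Of 9 tested genes 6 rose, 0 fell and 3 did not pass, and adjusted over the list alone 8 rose and 1 fell. The list was higher as a set (median 1.72, camera adjusted p = 5.68e-14; adjusted p = 0.132 with an estimated correlation). The call for Musk (edgeR adjusted p = 0.0142) was lost without WT replicate 1 (0.056) or WT replicate 2 (0.077). Those for Ache and Chrnb1 were lost with limma-voom (0.0734 and 0.0728) and without WT replicate 1 (0.076 and 0.0512), WT replicate 2 (0.111 and 0.116) or KO replicate 1 (0.093 and 0.1), and that for Chrnb1 without WT replicate 3 (0.0705).

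Of the 19 tested genes of atrophy and protein turnover, Ctsl, a lysosomal protease, rose and Foxo1, a transcription factor of the atrophy programme, fell, with the same counts adjusted over the list alone. The call for Foxo1 (log2 fold change -1.2, edgeR adjusted p = 0.0337) was lost without any 1 of WT replicates 2 and 3 and KO replicates 1 to 3 (edgeR adjusted p 0.054 to 0.149), and with DESeq2 (0.0654), limma-voom (0.0679) and library totals (0.0528). The muscle ubiquitin ligase genes Trim63 and Fbxo32 did not pass (log2 fold changes -0.56 and -0.47). Mstn did not pass in the main test (log2 fold change -1.40, edgeR adjusted p = 0.149). It passed as lower with limma-voom (0.0363), robust=FALSE (0.0319) and the slow-fibre score as a covariate (0.0292). Map1lc3a passed as lower with no filter (edgeR adjusted p = 0.0405) and without KO replicate 2 (0.023). The list did not pass (camera adjusted p = 0.705). Of 9 satellite cell and regeneration genes, Myog and Itga7 rose (2 rose and 1 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.163), though it passed as higher without WT replicate 1 (0.0273) or KO replicate 3 (0.0226). Myog, also on the neuromuscular junction list, rose by 3.64 on the log2 scale, against a median of 0.228 for this list. The list was not tested without Myog. The call for Itga7 (edgeR adjusted p = 0.0478) was lost with each library left out in turn (edgeR adjusted p 0.064 to 0.154) and with 7 other settings, DESeq2 among them (0.207).

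Among genes of energy metabolism, subunits of phosphorylase kinase fell. Phka1 and Phkb went from 158 ± 34.7 to 40.5 ± 9.03 CPM and from 232 ± 12.7 to 119 ± 32.0 CPM. Of 22 glycolysis and glycogen genes 4 fell, 3 rose and 15 did not pass, and adjusted over the list alone 8 fell and 3 rose. The genes that rose were Pfkfb3, a regulator of glycolysis, the glycolytic enzyme Gpi1 and the glycogen synthase Gys1; the calls for Gpi1 and Gys1 were lost with DESeq2 (adjusted p = 0.0617 and 0.11) and without WT replicate 1 or 2 or KO replicate 1 or 3 (edgeR adjusted p up to 0.158 and 0.195), and that for Gys1 without KO replicate 2 (0.058). A further subunit gene, Phkg1, also fell (edgeR adjusted p = 0.0125) and lost its call without WT replicate 2 (0.052) or WT replicate 3 (0.060) and with library totals (0.0536). The list passed (median -0.20, or 0.042 with library totals, camera adjusted p = 0.0276; adjusted p = 0.841 with an estimated correlation), and the call was lost with library totals (0.171) and without WT replicate 3 (0.277), KO replicate 1 (0.0561) or KO replicate 2 (0.223).

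Few genes of mitochondrial metabolism passed, at a depth where changes under 2-fold are often missed. Of 71 nuclear genes of oxidative phosphorylation 1 fell and 70 did not pass, with 0 adjusted over the list alone, and 4 passed as higher with library totals. On the TMM scale 61 of the 71 had a negative log2 fold change and 10 a positive one. The list was lower (median -0.13, camera adjusted p = 0.00926; adjusted p = 0.841 with an estimated correlation), and with library totals its median was 0.106 and it did not pass (camera adjusted p = 0.620), as without KO replicate 1 (0.315). Of the 13 mitochondrially encoded genes mt-Nd1 fell, from 26625 ± 2550 to 17814 ± 1506 CPM, and 7 fell adjusted over the list alone; the call for mt-Nd1 was lost without WT replicate 2 (edgeR adjusted p = 0.0545). All 13 had a negative log2 fold change on the TMM scale. That list was lower (median -0.35, or -0.12 with library totals, camera adjusted p = 0.000452; adjusted p = 0.841 with an estimated correlation). Of 18 genes of the tricarboxylic acid cycle Idh3a fell by 0.34 on the log2 scale and Idh2 rose by 1.29, from 91.0 to 224 CPM (the same counts adjusted over the list alone), and the call for Idh3a was lost with each library left out in turn (edgeR adjusted p 0.0501 to 0.166), with upper-quartile scaling, DESeq2, robust=FALSE and library totals (0.0588 to 0.486), and that for Idh2 without WT replicate 1, WT replicate 3 or KO replicate 1 (0.0741 to 0.177). Of 28 genes of fatty acid uptake and oxidation Hadh and Acadl rose (2 adjusted over the list alone), by 0.58 and 0.52 on the log2 scale, and both calls were lost in several settings: that for Acadl with each library left out in turn (edgeR adjusted p 0.0512 to 0.187) and with each scaling but library totals, DESeq2, limma-voom and robust=FALSE (0.0503 to 0.127), that for Hadh with 5 of the 6 libraries left out in turn (0.0514 to 0.164) and with DESeq2 (0.0595). With library totals Slc27a1 and Acadm passed as higher too (0.0227 and 0.0105), and 6 of the list in all. The last 2 lists did not pass (camera adjusted p = 0.573 and 0.300), and the fatty acid list passed as higher in KO without WT replicate 2 (0.0483).

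None of the 18 tested genes of the nuclear envelope and heterochromatin passed, over all genes or adjusted over the list alone, and the list did not pass (median 0.06, camera adjusted p = 0.680), though 2 passed as higher with library totals, and 1 as higher and 1 as lower with no filter. The list did pass the form of fry for either direction (adjusted p = 0.0103), which makes no comparison with other genes. Lmna, the gene of lamin A and C, had 25.0 ± 5.88 CPM in WT and 30.1 ± 9.11 CPM in KO, and Cbx5, of heterochromatin protein HP1 alpha, had 16.4 ± 2.92 and 16.5 ± 1.54 CPM. None of the 12 genes of the response to mechanical load and YAP passed either (median -0.14, or 0.10 with library totals, camera adjusted p = 0.573), and 1 passed as lower without KO replicate 1 and 1 with the slow-fibre score as a covariate.

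Of 9 clock genes Nr1d1 and Nr1d2, the REV-ERB repressors, fell from 50.2 ± 11.2 to 10.3 ± 4.35 CPM and from 32.8 ± 2.35 to 13 ± 3.78 CPM (2 fell and 1 rose in the list, or 2 and 2 adjusted over the list alone). Nr1d1 overlaps Thra, and the notes do not say whether strand was used in counting. Of 8 immediate early genes Jun fell (1 adjusted over the list alone; log2 fold change -1.01, edgeR adjusted p = 0.040), and the call was lost without any 1 of WT replicates 1 to 3, KO replicate 1 or KO replicate 3 (edgeR adjusted p 0.0607 to 0.161), and with library totals (0.0688) and the slow-fibre score as a covariate (0.052). Neither list passed (camera adjusted p = 0.627 and 0.215). The heat shock, interferon, cytosolic ribosome and cell cycle lists did not pass (camera adjusted p = 0.215, 0.931, 0.680 and 0.573), and 0 of their 14, 11, 64 and 3 tested genes changed, or 5 heat shock genes and no others adjusted over the list alone. With library totals 14 ribosome and 6 heat shock genes passed as higher. The ribosome list passed as higher with library totals (0.0211) and with fry (0.0155).

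In the main test no list of markers of other cell types passed, and in the alternatives at most 4 genes of such a list did. The macrophage and leukocyte list had a mean log2 CPM of 5.58, 4.83 and 4.05 in WT replicates 1 to 3 and 4.37, 4.31 and 4.65 in KO replicates 1 to 3, and 0 of its 16 genes passed (camera adjusted p = 0.0719). Without WT replicate 3 this list passed as lower in KO (camera adjusted p = 7.19e-08), as it did without KO replicate 3 (0.0226), and with all 6 libraries under no filter (0.0029), robust=FALSE (0.0486) and library totals (0.0158). The red blood cell list (5 genes) and the tendon list (6 genes) had 0 changed genes (camera adjusted p = 0.163 and 0.573) and passed as lower in KO without WT replicate 3 (9.38e-06 and 0.0319). In the adipocyte list (15 genes) Car3, which muscle also expresses, fell from 4765 to 1610 CPM (1 adjusted over the list alone) and lost its call without KO replicate 1, 2 or 3 (edgeR adjusted p 0.0672 to 0.142), and the list did not pass (camera adjusted p = 0.825). The lists of fibroblasts and extracellular matrix (25 genes), endothelium (15), smooth muscle and pericytes (10) and Schwann cells (4) had 0 changed genes, also adjusted over the list alone (camera adjusted p = 0.739, 0.825, 0.627 and 0.680). The endothelium list's median (-0.023) and its mean and test (0.035, higher) differed in sign. The Y-linked genes Ddx3y and Eif2s3y were read in all 6 libraries and did not pass (edgeR adjusted p = 0.528 and 0.546).

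**Figure D3:**
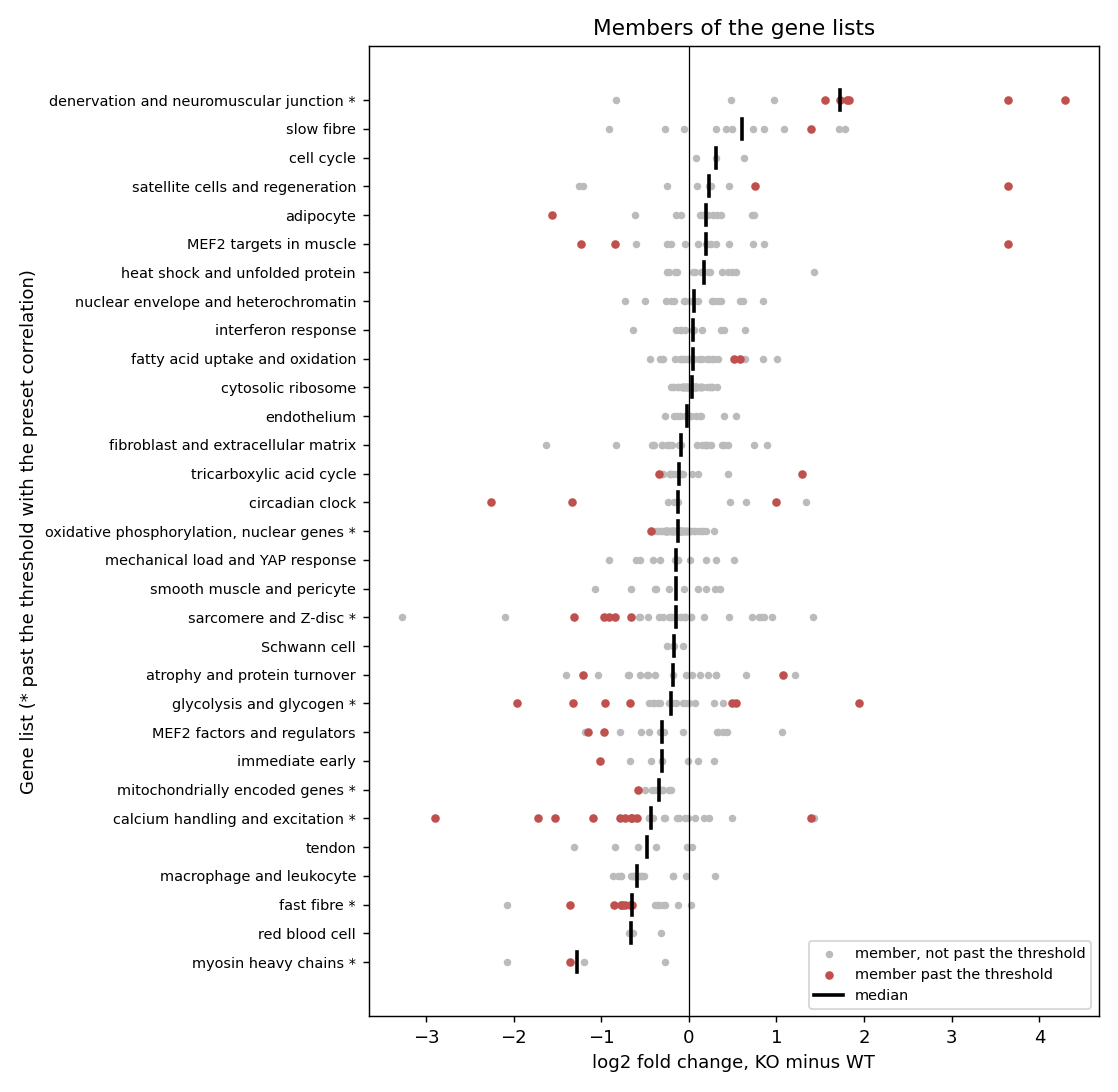
Each row is 1 of the 31 gene lists, each point a tested member at its log2 fold change (KO minus WT, horizontal axis), coloured where it passed the threshold, and the black bar is the median. The neuromuscular junction list has a median of 1.72, and the fast-fibre list a median of -0.65.

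The genes with the highest rises included Chrna9, a neuronal-type acetylcholine receptor subunit, which went from 0.958 ± 1.12 to 184 ± 57.4 CPM (log2 fold change 7.51, SE 0.47, edgeR adjusted p = 7.59e-06). It had 3, 0 and 1 counts in WT replicates 1 to 3 and 274, 218 and 432 in KO replicates 1 to 3. The size of its rise therefore rests on WT counts near the floor and is less certain than the SE. Fam174b had 2 counts over the WT libraries and 177 over the KO libraries, a ratio of 76.4 (exact 95% counting interval 20.8 to 636). Gm4841 and Cidea, a lipid droplet protein, had 3 counts each in WT against 59 and 50 in KO, with ratios of 17 (5.53 to 84.7) and 14.4 (4.65 to 72.1). Nqo1, an antioxidant enzyme, rose from 8.36 ± 2.90 to 55.4 ± 23.0 CPM. Wdfy1, Ppfibp2 and Ift122 rose by 3.09, 2.85 and 2.67 on the log2 scale. The call for Ift122 was lost without WT replicate 1, 2 or 3 (edgeR adjusted p 0.0733 to 0.109) and that for Ppfibp2, which overlaps Cyb5r2, was lost with limma-voom (0.0612).

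The largest falls included Flrt1, with 55 counts in WT and 0 in KO, at least 21.2-fold lower against 3 counts over the group. Flrt1 lies within Macrod1, which fell from 217 ± 72.9 to 17.1 ± 6.31 CPM, and reads of the pair may not be separable. Mss51, a muscle mitochondrial protein, had 146 counts in WT and 1 in KO, a ratio of 169 (29.9 to 6730). Mettl21c, a muscle methyltransferase, went from 51.1 ± 18.3 to 1.80 ± 1.22 CPM, Tspan8 from 151 ± 12.1 to 9.59 ± 3.67 CPM, and Asb5 and Asb15, of the ankyrin repeat and SOCS box family, from 355 ± 37.5 to 24.1 ± 11.7 CPM and from 28.5 ± 4.11 to 1.64 ± 1.54 CPM. Neu2, Mrln (the micropeptide myoregulin, which inhibits the calcium pump) and the kinase gene Mylk4 fell by 3.90, fell by 2.90 and fell by 2.89 on the log2 scale (edgeR adjusted p = 7.44e-05, 0.00562 and 0.0114).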

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

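The tests of the neuromuscular junction, slow-fibre and transcript length patterns were chosen after those results were seen.

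Reads outside the listed genes made up 3.91 ± 0.165% of the authors' library totals in KO and 3.36 ± 0.244% in WT, with each KO library above each WT library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). These reads entered no comparison, and which features they came from was not analysed here.

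The receptor and synapse genes (Chrna1, Myog, Lrp4, Musk, Ache, Chrnb1) were higher in KO. Scaling of the libraries is argued against, since the list's median log2 fold change was at least 1.7 under each scaling tried. Regenerating fibres stay open: Myh3 and Myh8 together reached at most 2.32% of the Myog level in a KO library, but no sample here gives their ratio in such fibres, and both are near the floor. Myh8 had 4, 2 and 2 counts in WT replicates 1 to 3 and 10, 11 and 6 in KO replicates 1 to 3, and Myh3 had at most 3 in a library. Loss of innervation stays open too: 6 further denervation genes had 33 counts in WT and 62 in KO, a pooled ratio of 1.62 (95% counting interval 1.05 to 2.55) against a Chrna1 fold of at least 13.3 at its lower 95% limit, but 2 of the 6 exceeded 10 KO counts, so the genes are near the floor. A direct effect of genotype was not tested and may hold as well.

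Slow-fibre genes were uneven between libraries of one genotype. Counting noise is argued against, with a median Pearson chi-square of 67.6 per degree of freedom, and since such noise is independent between genes. The genes deviated together within genotype, with a mean pairwise correlation between genes of 0.843 over the 6 deviations from the genotype means, above the 0.127 that marks the 95th percentile of 10000 expression-matched random lists, which is consistent with a different share of slow fibres in each dissected piece. Of the 30 other lists 6 were, like the slow-fibre list, lowest in replicate 3 of both genotypes. With 3 libraries per genotype some lists would do so by chance, and lists share genes, so the count alone shows no link to slow fibres. Of these 6, the tendon, mechanical load and adipocyte lists moved by 0.342, 0.265 and 0.261 log2 units per unit of the slow-fibre score. Their correlations with it were 0.882, 0.901 and 0.880 over the 6 deviations. The heat shock, endothelium and fatty acid lists moved by 0.105, 0.0694 and 0.0442, with correlations of 0.94, 0.93 and 0.622. The mechanical load list shares Ankrd2 and Csrp3 with the slow-fibre list, so part of its match can be built in. A wider difference between the pieces, or in their handling, was not tested and stays open beside slow fibres. The share of slow fibres is a hypothesis tested on the data that raised it, and a change of slow-fibre genes within fibres was not tested apart from it. With the slow-fibre score as a covariate 198 genes were higher and 223 lower, and 370 of the 418 calls were kept.

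Of the longest eighth of tested genes (transcripts from 5845 bases) 5.51% fell and 1.68% rose, against 2.96% and 3.17% of the others. The odds ratio of a fall was 1.91 (95% interval 1.34 to 2.68, Fisher's exact test p = 0.000356), and that of a rise 0.522 (0.278 to 0.903, p = 0.0162), in a test added after these percentages were seen that takes genes as independent, which they are not. The median lengths of 3210 bases for fallen and 2860 for risen genes were not separated by a permutation test (p = 0.0915). Shorter cDNA in the KO libraries is argued against, since fold change and transcript length had a Spearman rho of -0.016 across tested genes, and the longest eighth had a median log2 fold change of -0.022. GC content stays open: 100.7% of the median change of the fallen genes was left after the GC trend was removed, but fold change followed GC so weakly (rho 0.078) that removing it decides nothing. A link between genotype and long muscle genes may remain and was not tested.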

How the results depend on the processing

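Library totals and the slow-fibre covariate were chosen after seeing the data. No result past the threshold in either setting changed direction in any alternative. All 418 called genes had the same sign in every setting, and the count kept ranged from 228 (without WT replicate 2) to 416 (no filter). The libraries of the genotypes did not overlap for any of the 418, so leaving out a library could hardly change a sign. Of 2432 comparisons of named genes with an alternative, 2216 kept their side of the threshold, 172 lost it and 44 gained it; of 496 for lists, 466 kept it, 18 lost it and 12 gained it; 57 comparisons that passed in neither setting changed sign. Without a filter 344 genes were higher and 362 lower, with more genes tested. With library totals 653 were higher and 148 lower, by the shift of the scale. Leaving out each library gave 83 to 179 higher and 154 to 187 lower, with fewer samples: the count of higher genes was 101, 83 and 129 without WT replicates 1, 2 and 3. Lists past the threshold went from 8 to 0 with an estimated correlation and to 5 with fry (4 of the 8, and the ribosome list), and to 6 to 10 with a library left out. The adjusted p of the fast-fibre list was 0.416 with an estimated correlation and 0.0577 with fry; with fry the mitochondrially encoded, nuclear oxidative phosphorylation and glycolysis lists had 0.124, 0.369 and 0.369. That of the myosin heavy chain list was 0.227 with an estimated correlation (fry is a different test, against no change and not against other genes; with camera only the correlation was altered). The first principal component held 32.1% with no filter, 42.3% with the filter of 5 CPM in 3 libraries, 49.8% with library totals and 45.0 to 48.6% with a library left out; the cause was not tested. Prr14 ranged from -1.80 to -0.77 with a library left out and passed in no alternative. No paired analysis was possible because the titles share 1 animal number across genotypes and nothing says that it marks a pair. Depth limits genes under about 10 counts, Prr14 among them.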

Other observations

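The families in this part and the NRF2 test were chosen after their values were seen. Genes of polyamine metabolism were among those that fell. Odc1, the first enzyme of polyamine synthesis, went from 27.4 ± 1.18 to 8.43 ± 2.41 CPM (log2 fold change -1.69, SE 0.26, edgeR adjusted p = 0.000903, n = 3 each). Amd1, which makes the aminopropyl donor, went from 367 ± 115 to 79.3 ± 17.5 CPM and its near-identical copy Amd2 from 79.0 ± 18.4 to 15.3 ± 6.03 CPM, and reads of the pair may not be separable. Smox, spermine oxidase, fell by 1.05 on the log2 scale. Of 9 tested polyamine genes 4 fell and 5 did not pass. The 4 count Amd1 and Amd2 separately, though they may be 1 signal. Oaz2, whose product inhibits Odc1, passed as higher with no filter (edgeR adjusted p = 0.0177), without WT replicate 3 (0.0469) or KO replicate 3 (0.0385) and with library totals (0.00744), as did Sms with library totals (0.0283). In the Asb family of ubiquitin ligase adaptors, 5 of 11 tested members fell and 0 rose: Asb5, Asb15 and Asb14 (from 97.0 ± 20.7 to 15.5 ± 5.20 CPM), and Asb11 and Asb10 by less (-0.80 and -0.75), the call for Asb10 being lost without WT replicate 2 or 3 or KO replicate 1, 2 or 3 (edgeR adjusted p 0.0506 to 0.196), and with DESeq2 (0.087), limma-voom (0.0678), robust=FALSE (0.0572), library totals (0.113) and the slow-fibre score as a covariate (0.0631). Asb2 passed as higher with no filter (4.33e-05), without KO replicate 1 (0.0401) and with library totals (0.0188).

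Several antioxidant genes were higher in KO: Nqo1, Srxn1 (from 18.3 ± 9.50 to 72.3 ± 3.63 CPM), Pir, Cat (from 73.6 ± 15.8 to 265 ± 62.1 CPM) and Gstp2. A shared response of targets of the transcription factor NRF2 is a candidate explanation. Among the NRF2 targets other than these 5, 14 were tested, 3 rose (Txnrd1, Txn1 and Fth1), Me1 fell, and the median log2 fold change was 0.35. Leaving out 1 library ended the calls for Fth1 (without WT replicate 1 or 2, edgeR adjusted p 0.0901 and 0.142), Txn1 (without WT replicate 2 or 3 or KO replicate 3, 0.0562 to 0.151) and Me1 (5 of the 6 libraries, 0.0583 to 0.15). The call for Me1 was also lost with DESeq2 (0.0879), limma-voom (0.0544), robust=FALSE (0.0504) and library totals (0.0711). With library totals, which move the median of all tested genes to 0.251, Prdx1, Gsta4, Gstm1 and Aox1 passed as higher (0.00342, 0.016, 0.0178 and 0.026), Prdx1 and Aox1 also with no filter (0.0336 and 0.0414). As a set they passed with the preset correlation (camera p = 0.0122) and not with an estimated one (camera p = 0.167), so the hypothesis stays open. A wider list that also held Cbr1, Gpx2, Osgin1 and Esd was run first and gave camera p = 0.00213 with the preset and 0.118 with an estimated correlation.

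Genes near Prr14 were not found to change more often than others. Within 10 Mb, 5 of 86 tested genes passed (5.81%) against 413 of 6593 elsewhere (6.26%, two-sided Fisher's exact test p = 1), and windows of 5 and 20 Mb gave p = 0.781 and 0.621. The nearest of the 5 was Mylpf, which fell, at 0.245 Mb from Prr14. Fam57b rose by 2.24 on the log2 scale at 0.629 Mb. The others were Mvp (0.445 Mb), Nsmce1 (1.97 Mb) and Bccip (6.23 Mb), whose calls were each lost with at least 4 of the 6 libraries left out in turn.

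The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes, 1 of the 10 splits, the real one, gave as many as 418, and the highest other split gave 2. For gene lists, 5 of the 10 splits gave at least the 8 lists of the real split, and the highest other gave 16. Each other split sets 2 libraries of a genotype and 1 of the other against the rest. The genotype difference then widens the spread within its groups, which lowers the gene calls whatever set the genotypes apart. The 418 against 2 is therefore no measure of calls without a genotype difference. Part of that difference also stays between the groups, and what gives these list calls was not tested.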
